A study of Pimephales promelas with 27 samples.

How the data were processed

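RNA of cultured fathead minnow ovary explants was measured on 27 Agilent 1-colour arrays, 1 sample per array, on 7 slides scanned on 3 days. Per the labels, RNA was extracted with TRIzol, its integrity number (RIN) ranged from 6.5 to 8.3 (7.45 ± 0.55), samples below 7.5 were purified on columns, and only samples above 7.5 after that were used. RNA was labelled with Cy3. Per the file headers, the authors' scanner files came from Agilent Feature Extraction 10.7.1.1 and give each spot's processed signal as a linear intensity after background subtraction and detrending, with the median intensity of the spot and of its local background. Per the file headers, these files also hold other columns, flags of 0 or 1 for spots well above background, saturated or non-uniform. The deposited table of the authors holds log2 values whose normalization is not stated. Each of its columns was correlated with the log2 processed signal of its own array, the lowest r being 0.9976 (across spots), with column medians from 8.13 to 8.20.

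Each array held 15744 spots, 536 of them controls. The log2 processed signal of the 15208 non-control probes was set relative to the array's 75th percentile. Left out were 169 probes with a non-uniform or population flag on any array and 1333 probes well above background on fewer than 4 arrays, sets that overlap in part. The remaining 13714 probes were tested. Signal ranged over arrays from a 75th percentile of 921 to 5709, and between 73.9% and 89.9% of the probes were well above background. The number of arrays limits the precision.

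Groups were the agent and time given by the labels. Before the data were examined, the comparisons of DHT with control, of the controls over time, the threshold, the filter and all but the added alternatives were fixed. One group-means model of the 6 groups over the 27 arrays was fitted with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with contrasts, moderated statistics and Benjamini-Hochberg adjustment over the tested probes of each contrast, at an adjusted p under 0.05. Intervals are at 95%. The interaction of agent and time was tested with limma's moderated F. The model was tested on simulated data with 200 changed probes, where it made between 4 and 10 false calls per comparison. The simulated arrays were drawn independently, without the pairing found in the real ones. These counts therefore do not give the false calls in the real data. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

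The planned rule for named genes and the planned gene lists, cell type markers included, were not run, since the files do not pair probes with genes. Of the probe names, 11862 were contigs, 3309 carried a sequence number and 37 were other clone names, and 0 matched any of the 64593 entries of the reference table. In place of genes, probes are named by a rule set after the data were seen. It takes the 2 called probes with the largest rise and the 2 with the largest fall for each time comparison in controls, and the 2 with the smallest p in each direction for each DHT comparison, said not to pass. A probe not well above background on any array of a group is given by a floored change. Its level on each array of that group was raised to at least the lowest of any probe well above background there. This is no lower bound where arrays of the other group were also not well above background.

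The alternatives fixed in advance were normexp background correction of the median signal (offset 50) with quantile normalization, quantile normalization of the processed signal, the deposited log2 values, no filter on dim probes, only probes well above background on all arrays, slide as a fixed or random block, only the arrays compared, and leaving out each array. The median signal replaced the planned mean signal, which the scanner files do not hold. Chosen after the data were seen were scan day as a block, inferred pairs of arrays as a block and the time comparisons in the DHT arrays. Pairs were mutual best partners within a time at r over 0.5. The first set used deviations from the mean of the time over 500 variable probes, without the agent labels. The second used deviations from the group means over probes well above background on all arrays. The agents were relabelled within times in 1e+05 draws with seed 11. Up to 100 splits of the arrays were fitted for each comparison, with other fixed seeds.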

Results

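The series measured RNA in pieces of fathead minnow (Pimephales promelas) ovary kept in culture as explants. Explants were held for 6, 9 or 12 h without treatment or with DHT (dihydrotestosterone, an androgen) at 1e-06 M. Each of the 27 arrays held 1 sample, with 4 control and 5 DHT samples at 6 h, 5 and 5 at 9 h, and 4 and 4 at 12 h. Of 15208 non-control probes on the array, between 11241 and 13672 were well above background on a given array. The 75th percentile of the processed signal ranged from 921 to 5709 between arrays, and no non-control probe was saturated. The number of arrays limits the precision of every value here. The labels do not say whether the explants of a group came from separate fish, so that p-values measure only the spread between these samples. Probes are given by their IDs, since the files do not pair them with genes. Levels are log2 signals relative to the 75th percentile of the same array.

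The first question was whether DHT changed transcript levels at each time of culture. After 6 h, no probe passed the threshold. UF_Ppr_AF_115298 had the smallest p of those with a higher mean with DHT. Its mean was -7.04 ± 0.44 (SD, n = 5) with DHT and -8.83 ± 0.27 (SD, n = 4) in controls (limma adjusted p = 0.286). It was not well above background on any control array and was so on 4 of the 5 DHT arrays. Its floored change was 1.03-fold, which is no lower bound. UF_Ppr_AF_108920 was next, at 2.11 (SE 0.58, limma adjusted p = 1), and at 1.45 without DHT 6 h replicate 2. With lower means, UF_Ppr_AF_112943 differed by -0.68 (SE 0.24, and -0.44 without control 6 h replicate 2) and UF_Ppr_AF_102252 by -1.02 (SE 0.36), both with a limma adjusted p of 1. Slide 2 was the one slide with both arms at 6 h, with 4 DHT arrays and control 6 h replicate 2 as its only control. There the differences of the last 3 were 2.39, -1.44 and -0.74. These rest on arrays already used above, DHT 6 h replicate 2 among them, and are no separate evidence. Normexp gave smaller differences for UF_Ppr_AF_108920 (1.41), UF_Ppr_AF_112943 (-0.26) and UF_Ppr_AF_102252 (-0.34), the last well above background on 3 of the 4 control arrays. limma called 0 of 13714 probes at an adjusted p under 0.05, and 59 had an unadjusted p under 0.05 where 685.7 are expected by chance.

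After 9 h, the probes with the smallest p among those higher with DHT were UF_Ppr_AF_113682, at 0.85 (SE 0.29), and UF_Ppr_AF_104685, at 0.36 (SE 0.13). Among those lower with DHT they were UF_Ppr_AM_119322 and UF_Ppr_AF_112362, the latter at -0.79 (SE 0.22). None of the 4 passed, each with a limma adjusted p of 1.00. UF_Ppr_AM_119322 was not well above background on any DHT array and was so on 2 of 5 control arrays. Its floored change was 1.27-fold, which is no lower bound, and its smallest log2 difference over the alternatives was -0.22. UF_Ppr_AF_113682 was well above background on 1 of 5 control and 3 of 5 DHT arrays, and normexp gave it a difference of 0.22. Of 4 slides with both arms at 9 h, UF_Ppr_AF_112362 was lower with DHT on 3 (-1.06, -1.02 and -0.48) and not on slide 2 (0.09). Its difference was -0.35 after normexp and -0.50 with the first set of inferred pairs as a block. The differences within slides ranged from 0.04 to 0.62 for UF_Ppr_AF_104685. For UF_Ppr_AF_113682, only slide 3 had arrays of both arms well above background, with a difference of 0.41, and for UF_Ppr_AM_119322 no slide had. limma called 0 of 13714 probes. An unadjusted p under 0.05 was found for 361 probes, 317 of them lower with DHT.

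After 12 h, UF_Ppr_AF_105636 was higher with DHT by 0.99 (SE 0.24, and 0.43 after normexp) and UF_Ppr_AF_113336 by 0.73 (SE 0.19). UF_Ppr_AF_117085 differed by -2.22 (SE 0.51), by -1.58 without control 12 h replicate 4 and by -0.50 after normexp. UF_Ppr_AF_109091 had a mean of -3.94 ± 0.14 (SD, n = 4) with DHT and -2.85 ± 0.20 (SD, n = 4) in controls, a difference of -1.08 (SE 0.25). All 4 missed the threshold, each with a limma adjusted p of 1.00. UF_Ppr_AF_117085 was well above background on 3 of 4 control arrays and 1 of 4 DHT arrays. On slides 5 and 7, the 2 slides with both arms at 12 h, the differences were 1.03 and 0.58 for UF_Ppr_AF_105636, 0.83 and 0.55 for UF_Ppr_AF_113336, and -0.99 and -1.01 for UF_Ppr_AF_109091. For UF_Ppr_AF_117085, no array of slide 5 was well above background. Its difference on slide 7 was -3.12, where DHT 12 h replicate 4 was not well above background either, so this size is uncertain. limma called 0 of 13714 probes, and 381 had an unadjusted p under 0.05, 154 higher and 227 lower.

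An effect shared by the times was sought in the mean of the 3 differences. UF_Ppr_AF_115298 and UF_Ppr_AF_105636 (0.48, SE 0.13, and 0.21 after normexp) had the smallest p among probes higher with DHT. No size is given for UF_Ppr_AF_115298, since it was well above background on 0 of 4 control arrays at 6 h and 0 of 5 DHT arrays at 9 h. UF_Ppr_AF_109325 (-0.86, SE 0.21) and UF_Ppr_AF_117085 (-1.07, SE 0.28) had it among probes lower with DHT, and normexp gave these differences of -0.22 and -0.24. UF_Ppr_AF_109325 was well above background on 3 of 5 DHT arrays at 9 h and 2 of 4 at 12 h, and UF_Ppr_AF_117085 on 1 of 4 control arrays at 6 h and 1 of 4 DHT arrays at 12 h. The limma adjusted p was 0.910 for each of the 4. limma called 0 probes, and 710 had an unadjusted p under 0.05, 139 higher and 571 lower. The test of whether the DHT effect differed between times also called 0 probes by limma, with 74 at an unadjusted p under 0.05. The interval of the averaged effect lay within a 2-fold change either way for 86.9% of the probes, against 65.9% at 6 h, 62.0% at 9 h and 57.3% at 12 h. No fit with other values, filters or with slide as a fixed or random block called a probe for DHT. Of 2 fits with pairs of arrays inferred from the data as a block, both chosen after the data were seen, limma called 0 probes in the average with 1 set of pairs and 9 with the other, which also called 1 probe at 6 h. In simulated arrays with the spread of these data, 41% of probes changed 2-fold were recovered at 6 h, 48% at 9 h, 40% at 12 h and 71% in the average. The simulated arrays were drawn independently, without the pairs described next. These shares therefore do not give the recovery in the real arrays. Arrays of both arms resembled each other in pairs, as a measured fact that bears on these tests. Over 500 variable probes, 10 control arrays each had 1 DHT array of the same time as mutual best partner, at r from 0.76 to 0.96 (across probes, which are not independent replicates). These probes were picked for their spread. Over the other 13214 probes, r of the 10 pairs was 0.35 to 0.78, and 8 of them were again mutual best partners. Control 12 h replicate 3 with DHT 12 h replicate 2, and control with DHT 12 h replicate 4, were not.

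**Figure D1:**
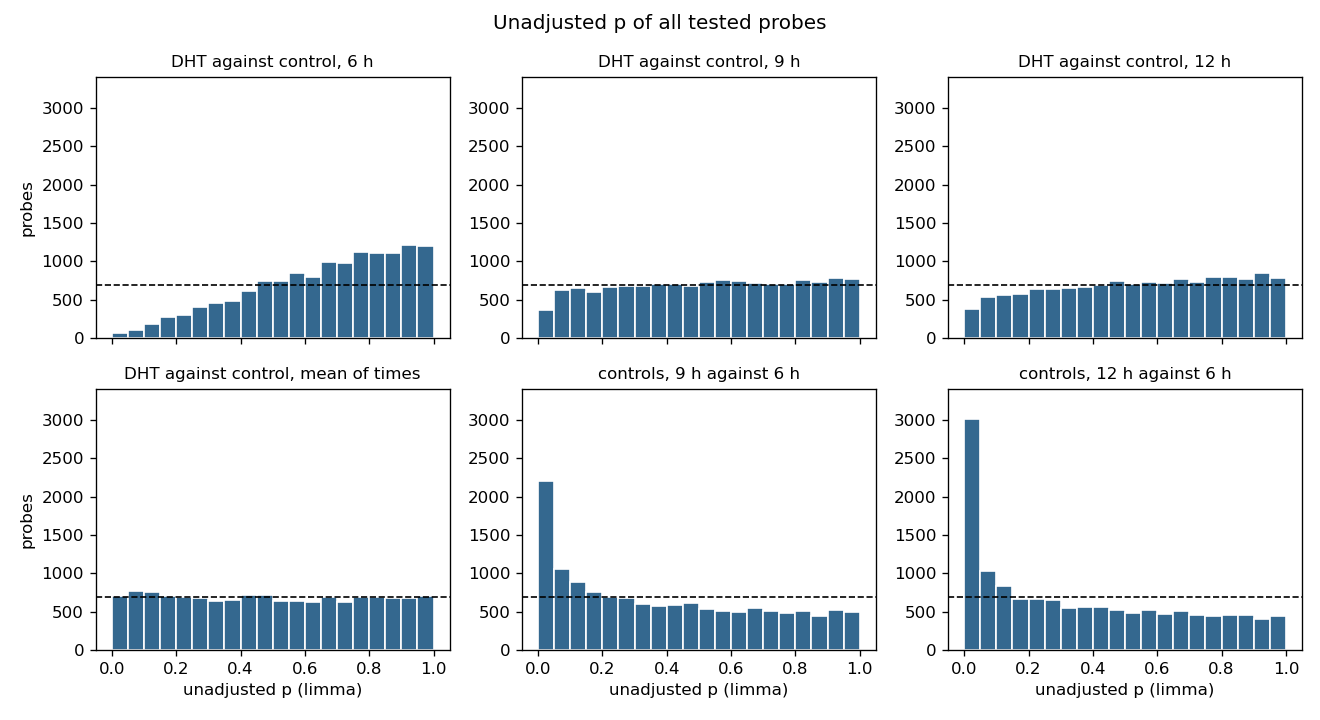
Histograms of the unadjusted limma p of the 13714 tested probes (x axis, p in 20 bins; y axis, number of probes) for 6 comparisons, with the count expected by chance in each bin (685.7) as a dashed line. The lowest bin lies below that line for DHT at 6, 9 and 12 h (59, 361 and 381 probes) and above it in the controls at 9 h (2207) and 12 h (3020) against 6 h.

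Change in culture without DHT was compared as background. Between 6 and 9 h, UF_Ppr_AF_116027 rose in controls from -6.71 ± 1.06 (SD, n = 4) to -3.79 ± 0.41 (SD, n = 5), a log2 change of 2.92 (SE 0.46, limma adjusted p = 0.00411), and the ranges did not overlap. It was well above background on 3 of the 4 control arrays at 6 h. UF_Ppr_AF_100947 rose from -9.10 ± 0.87 (SD, n = 4), not well above background on any array, to -6.16 ± 1.00 (SD, n = 5), well above background on 3 of 5. The limma adjusted p of this rise was 0.0238. Its floored change was 1.88-fold, which is no lower bound, and its smallest log2 rise over the alternatives was 0.79. UF_Ppr_AF_111538 fell by 3.50 on the log2 scale (SE 0.81, limma adjusted p = 0.0350), from 0.88 ± 1.86 (SD, n = 4) to -2.62 ± 1.37 (SD, n = 5). UF_Ppr_AF_116100 fell by 3.39 on the log2 scale (SE 0.76, limma adjusted p = 0.0295), from 2.26 ± 1.41 (SD, n = 4) to -1.13 ± 1.70 (SD, n = 5). The ranges of both falling probes overlapped between the times. A fit to the control arrays alone ended all 4 calls, at limma adjusted p of 0.0653 for UF_Ppr_AF_116027 (0.00225 to 0.0653 over its alternatives), 0.0882 for UF_Ppr_AF_100947 (0.0107 to 0.138), 0.163 for UF_Ppr_AF_111538 (0.0160 to 0.163) and 0.151 for UF_Ppr_AF_116100 (0.0187 to 0.151). Normexp ended the call of UF_Ppr_AF_100947 (limma adjusted p = 0.138) and gave UF_Ppr_AF_116027 a change of 1.61 (limma adjusted p = 0.00636). Without control 6 h replicate 4 the change was -4.35 for UF_Ppr_AF_111538 and -4.07 for UF_Ppr_AF_116100, and without control 9 h replicate 2 it was -2.73 for the latter. Leaving out 1 array ended the call of UF_Ppr_AF_100947 for control 6 h replicate 1, 2 or 4 (limma adjusted p 0.0633, 0.0947 and 0.0503) and control 9 h replicate 1 (0.0678). It ended that of UF_Ppr_AF_111538 for control 6 h replicate 1, 2 or 3 (0.111, 0.135 and 0.0740) and control 9 h replicate 1 or 2 (0.0869 and 0.0590), and that of UF_Ppr_AF_116100 for control 6 h replicate 1, 2 or 3 (0.108, 0.103 and 0.0737) and control 9 h replicate 1 or 3 (0.0668 and 0.0527).

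The DHT arrays share no array with the controls but pair with them as described above, so they are no independent repeat of the comparison. In the DHT arrays UF_Ppr_AF_116027 rose by 2.37 (SE 0.43, limma adjusted p = 0.0137). UF_Ppr_AF_111538 fell by 4.50 (SE 0.77, limma adjusted p = 0.00843) and UF_Ppr_AF_116100 fell by 4.23 (SE 0.72, limma adjusted p = 0.00843). UF_Ppr_AF_100947 differed by 1.28 (SE 0.58), which did not pass (limma adjusted p = 0.300), and was well above background on 2 of 5 arrays at 6 h and 4 of 5 at 9 h. At 12 h, the control mean of UF_Ppr_AF_116027 was -6.10 ± 0.52 (SD, n = 4), while UF_Ppr_AF_111538 differed from 6 h by -2.88 (limma adjusted p = 0.0323) and UF_Ppr_AF_116100 by -2.96 (limma adjusted p = 0.0183). The arrays of 12 h lay on slides and scan days of their own, so batch and time cannot be told apart in these values.

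**Figure D2:**
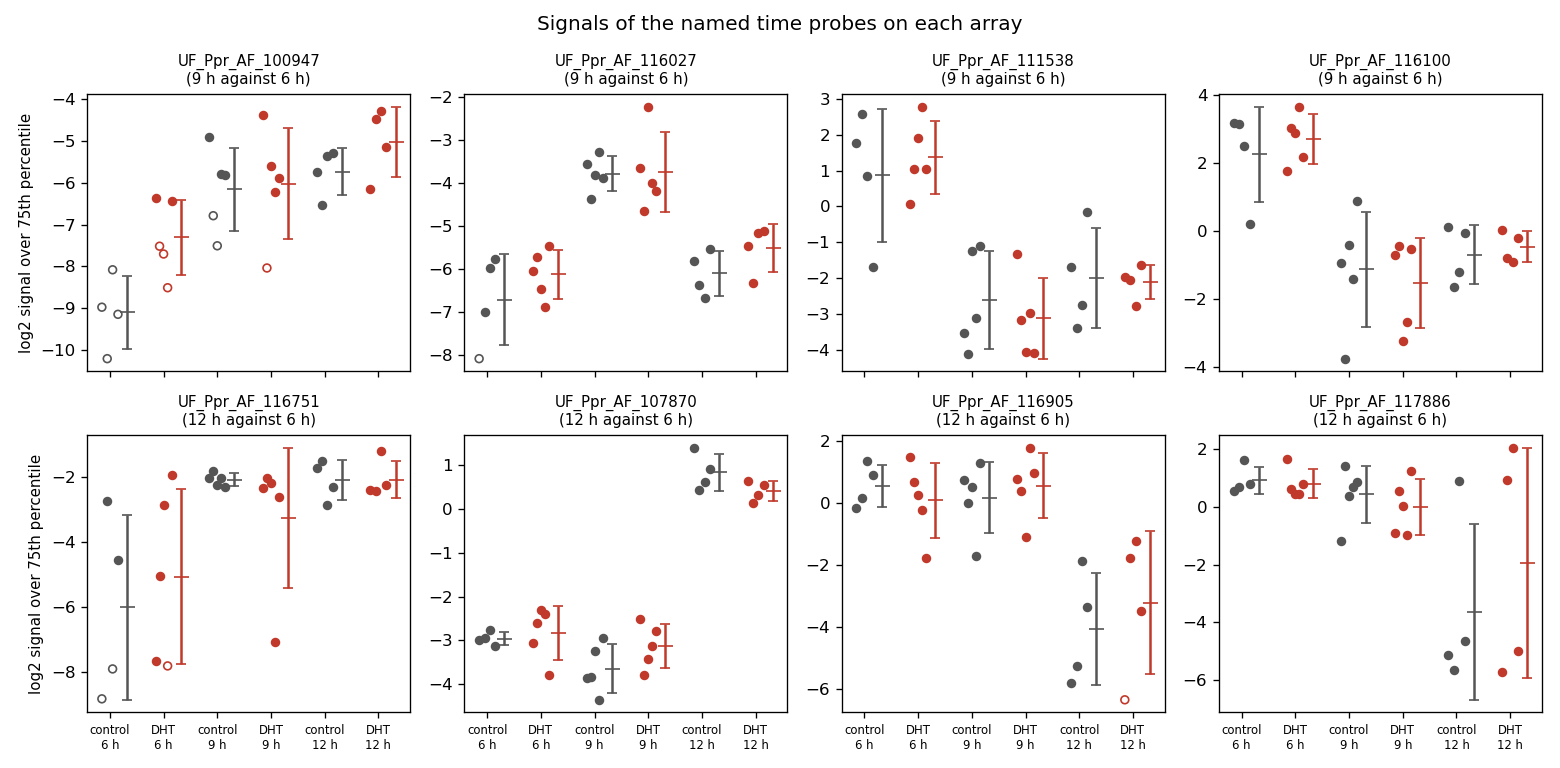
Log2 signal relative to the 75th percentile of the array (y axis) of the 8 probes named for the time comparisons, in the 6 groups (x axis), with controls in grey and DHT in red. Each point is 1 array, open where the probe was not well above background, and bars give the mean and SD. UF_Ppr_AF_116027 was near -3.79 in controls at 9 h and -6.71 and -6.10 at 6 and 12 h, and UF_Ppr_AF_107870 rose to 0.84 at 12 h.

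In all, limma called 176 of 13714 probes between 6 and 9 h in controls at an adjusted p under 0.05, 65 higher and 111 lower. The median change was 1.97-fold for the probes that rose and 1.70-fold for those that fell. All 176 moved the same way in the DHT arrays, where 171 had an unadjusted p under 0.05. Of the 109 probes called in the DHT arrays, 69 were among the 176. Slides 1, 2 and 4 held both times. The named falls were uneven between these slides, at -5.61, -3.81 and -0.68 for UF_Ppr_AF_111538 and at -5.54, -3.55 and -0.47 for UF_Ppr_AF_116100. Within-slide changes were 4.11, 3.19 and 1.98 for UF_Ppr_AF_116027, which was not well above background on the 6 h array of slide 1. With slide as a block, 357 probes were called, and a fit to the control arrays alone, with fewer arrays behind the spread, called 2. The main fit counts the paired arrays of both arms as separate samples, so its p-values may be too small. How far this accounts for the fall to 2 was not tested. The deposited values gave 94 higher and 76 lower, where the main values gave 65 and 111. Leaving out control 6 h replicate 1, 2, 3 or 4 left 35, 31, 67 or 82 calls, and leaving out control 9 h replicate 1, 3 or 5 left 41, 46 or 93. The 109 calls in the DHT arrays became 20 with slide as a fixed block. They became 28, 14, 30 or 15 without DHT 6 h replicate 1, 2, 3 or 4, and 64, 229, 24, 14 or 55 without DHT 9 h replicate 1, 2, 3, 4 or 5.

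Between 6 and 12 h, UF_Ppr_AF_107870 rose in controls from -2.96 ± 0.15 (SD, n = 4) to 0.84 ± 0.42 (SD, n = 4). This was a log2 change of 3.80 (SE 0.32, limma adjusted p = 6.58e-08), or 13.9-fold, and the rise in the DHT arrays was 3.25 (SE 0.31, limma adjusted p = 1.39e-07). UF_Ppr_AF_116751 was higher by 3.91 (SE 1.26, limma adjusted p = 0.04997), but it was well above background on only 2 of the 4 control arrays at 6 h. Its 6 h levels went with the inferred pairs. They were -2.75 in control replicate 2 and -2.87 in its partner, DHT replicate 3. In the other pairs of 6 h, both arrays lay between -8.83 and -7.67. A difference between samples rather than times was not tested. UF_Ppr_AF_116905 fell by 4.62 on the log2 scale (SE 0.96, limma adjusted p = 0.00218), from 0.55 ± 0.68 to -4.07 ± 1.80 (SD, n = 4 each), with no overlap of the ranges. In the DHT arrays UF_Ppr_AF_116905 fell by 3.29 (SE 0.91, limma adjusted p = 0.0185). UF_Ppr_AF_117886 fell by 4.56 on the log2 scale (SE 1.35, limma adjusted p = 0.0321). In the DHT arrays UF_Ppr_AF_117886 differed by -2.74 (SE 1.28, limma adjusted p = 0.202) and UF_Ppr_AF_116751 by 2.98 (limma adjusted p = 0.123), neither of which passed, and DHT 12 h replicates 2 and 3 stood at 0.94 and 2.03 for UF_Ppr_AF_117886. Control 12 h replicate 3, the inferred partner of DHT 12 h replicate 2, stood at 0.89 for UF_Ppr_AF_117886. The mean of this probe over the 12 h controls was -3.64 ± 3.05 (SD, n = 4). In the other pairs of 12 h, both arrays lay between -5.72 and -4.65. The pairs were set on variable probes of these same arrays, so this likeness is no separate evidence. The calls of UF_Ppr_AF_116751 and UF_Ppr_AF_117886 ended under other settings, with UF_Ppr_AF_116751 at a limma adjusted p of 0.0834 after quantile normalization (0.0134 to 0.209 over its alternatives) and UF_Ppr_AF_117886 at 0.0503 after normexp (0.00249 to 0.110). Leaving out 1 array ended the call of UF_Ppr_AF_116751 for control 6 h replicate 1 or 3 (limma adjusted p 0.209 and 0.152) and control 12 h replicate 1, 2, 3 or 4 (0.116, 0.0961, 0.0691 and 0.0860). It ended that of UF_Ppr_AF_117886 for control 6 h replicate 1, 2, 3 or 4 (0.0655, 0.0591, 0.0750 and 0.0583) and control 12 h replicate 1, 2 or 4 (0.110, 0.0938 and 0.0867). The change was 2.97, 5.00 or 3.28 for UF_Ppr_AF_116751 without control 6 h replicate 1, 2 or 3, and 2.21 after normexp. It was -3.89 or -6.07 for UF_Ppr_AF_117886 without control 12 h replicate 2 or 3, and -3.90 after normexp. The calls of UF_Ppr_AF_107870 and UF_Ppr_AF_116905 passed under each alternative tried, the latter at -5.35 without control 12 h replicate 3. The 12 h levels of UF_Ppr_AF_116905 also went with the inferred pairs. They were -5.79 and -6.33 in replicates 1 of control and DHT, and -3.35 and -3.48 in replicates 4. In control replicate 3 and DHT replicate 2 they were -1.88 and -1.79. How far samples rather than times set the size of this fall was not tested.

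limma called 1372 of 13714 probes between 6 and 12 h in controls, 1198 higher and 174 lower. The median change was 2.42-fold for probes that rose and 1.57-fold for those that fell. Of the 1198 probes that rose, 853 (71.2%) were well above background on all arrays. By mean level, they were 200 of 2622 tested probes below -6, 478 of 2760 from -6 to -4, 372 of 2642 from -4 to -2, 102 of 2043 from -2 to 0 and 46 of 3647 above 0. The median change of all tested probes in these bins was 0.38, 0.42, 0.24, 0.04 and -0.09 in controls and 0.32, 0.35, 0.23, 0.02 and -0.08 in the DHT arrays. In the DHT arrays, limma called 1478 probes, 1325 higher and 153 lower, and 1042 probes were called in both arms, which pair and are not independent. Of the 1372 control calls, 1370 had the same sign in the DHT arrays. The median of all tested probes was 0.12 higher at 12 h than at 6 h in controls under the main scaling and -0.02 under quantile normalization. Relative to that shift, quantile normalization called 848 probes, 638 higher and 210 lower, normexp 870, 654 higher and 216 lower, and the deposited values 788. With slide as a random block, 1290 were called. The arrays of 12 h lay on slides and scan days that held no other time, so batch and time cannot be told apart in this comparison. Leaving out control 6 h replicate 1 or control 12 h replicate 1 left 848 or 900 calls.

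**Figure D3:**
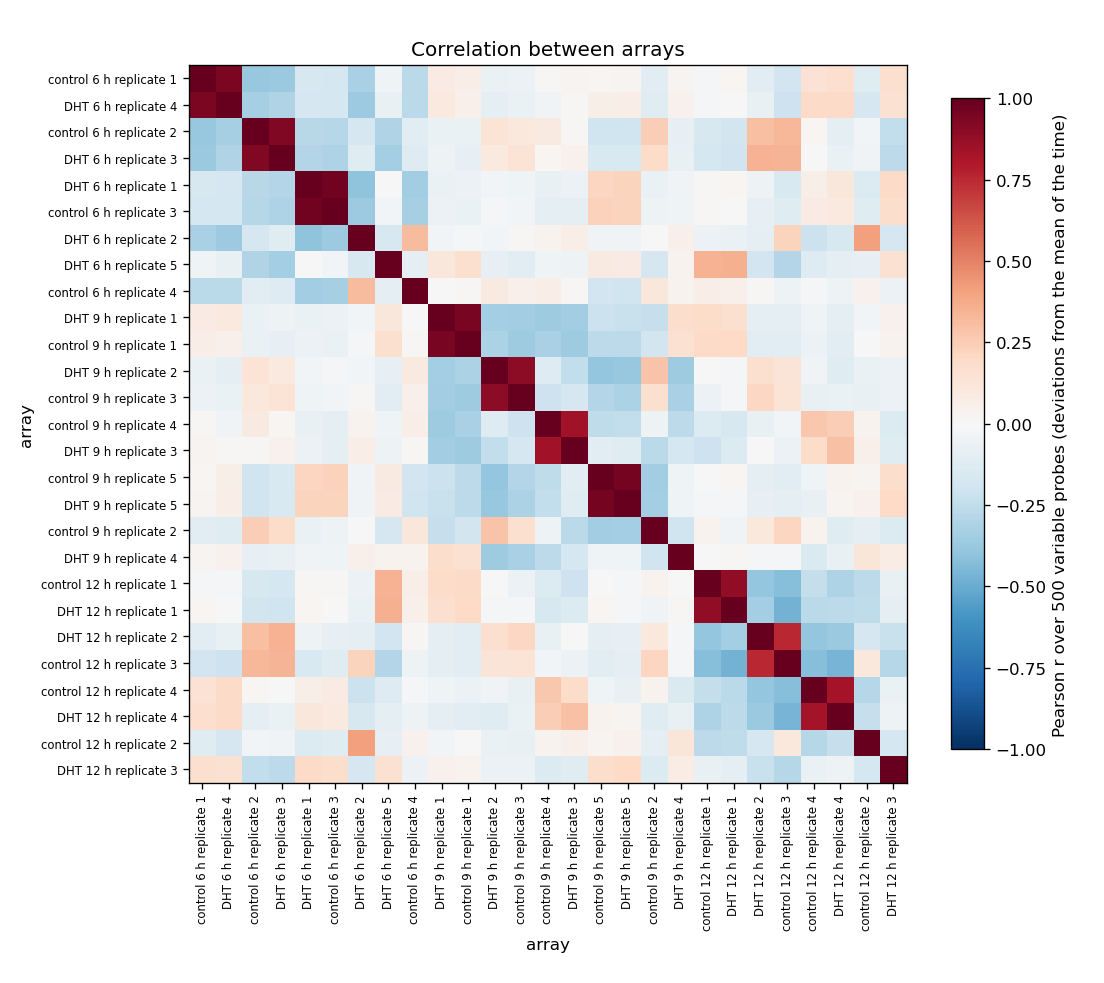
Pearson correlation between each pair of the 27 arrays over 500 variable probes, as deviations from the mean of the time (both axes list the arrays, ordered by time with partners side by side; colour gives r from -1 to 1). The 10 dark red blocks beside the diagonal are a control and a DHT array of the same time, at r from 0.76 to 0.96, while other arrays of a time reached at most 0.31.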

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

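The splits of the arrays for the DHT comparisons at single times and their average, the tests of the inferred pairs and of their swaps, and the tests of lower signal and batch at 12 h were chosen only after the results were seen. Of 58 groups of 4 or 5 values tested for an array far from the rest of its group, 5 held one, where 2.9 are expected by chance. DHT 6 h replicate 2 had a median correlation with its own group of 0.938, and DHT 12 h replicate 1 of 0.956, each below the others. UF_Ppr_AF_115298 stood at -9.24 on control 6 h replicate 2, below its group. UF_Ppr_AF_112362 stood at -4.81 on control 9 h replicate 2, above its group. UF_Ppr_AF_117886 stood at 0.89 on control 12 h replicate 3, above its group, and at 0.94 on the inferred partner of that array, DHT 12 h replicate 2.

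For the DHT comparisons limma called 0 probes, a count that every split reaches (100 of 100 at 6 h, 100 of 100 at 9 h, 35 of 35 at 12 h, 100 of 100 for the average and 100 of 100 for the interaction), so that these counts of calls decide nothing about chance. The highest counts of the other splits were 102, 1234, 55, 229 and 37. Nor do the probes with an unadjusted p under 0.05 settle it, since splits that part fewer of the inferred pairs than the real one give higher counts. There, 99 of 100 splits reached the 59 probes at 6 h, 66 of 100 the 361 at 9 h, 21 of 35 the 381 at 12 h, 34 of 100 the 710 of the average and 99 of 100 the 74 of the interaction. The splits that called many probes point to a structure of the samples beyond agent and time.

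By the number of probes called, only the real split reached each time comparison. This argues against a chance split of the arrays but does not exclude one, since no share below 1 of 100 or 1 of 35 was possible. The splits also treat arrays as separate samples, and the labels do not say whether explants share a fish. In controls, 176 probes were called between 6 and 9 h, which 1 of 100 splits reached (the real one), with 60 as the highest other. Between 6 and 12 h, 1372 were called, which 1 of 35 splits reached, with 44 as the highest other. In the DHT arrays, 109 were called at 9 h, which 1 of 100 splits reached, with 5 as the highest other, though 3 of 100 reached its 2034 probes with an unadjusted p under 0.05 and the highest other had 2124. At 12 h 1478 were called, which 1 of 100 splits reached, with 984 as the highest other, from a split that put 1 array of 6 h with the arrays of 12 h.

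Arrays paired across agents, with 10 pairs of mutual best partners, all 10 of a control and a DHT array, where relabelled agents gave 5.61 on average (permutation p = 0.005). Sharing a slide is argued against as the only cause, since 3 pairs lay on different slides and reached r of 0.76 to 0.96. The highest r of 2 arrays of a slide and time that were not partners was -0.0504, but the best matches had been taken out of these. All other pairs lay on 1 slide each, at r of at least 0.83, so a part played by the slide stays open. A shared source, such as explants of the same fish, may account for the 10 pairs, though the labels do not give one. Matched arms could also leave fewer small p-values than chance, but the splits cannot test this. Over splits the probes with p under 0.05 fell with the number of pairs parted, with a rank correlation of -0.78 at 6 h, -0.62 at 9 h and -0.89 at 12 h (permutation p = 1e-05 each, the smallest the draws can give, over splits that share arrays). The pairs were chosen as the most alike arrays of these same data, so a fall was largely fixed in advance. Among splits that part every pair, 18 of 19 at 6 h, 4 of 15 at 9 h and 0 of 7 at 12 h had as many such probes as the real split.

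With the second set of inferred pairs as a block, limma called 9 probes for DHT averaged over times, 3 higher and 6 lower, and with the first set it called 0 of the 9, at a smallest adjusted p of 0.131. A chance swap of agent within pairs stays open, since these pairs were set with the agent labels, which favours the real labels: 1 of 100 draws reached 9, the real one, with 1 as the highest other, and 2875 probes had an unadjusted p under 0.05 against 2839 in the highest other draw, while 5 of 100 draws reached the 1 call at 6 h. Signal near background stays open too, since 4 of the 9 were not well above background on every paired array. The choice of normalization cannot be told apart, with 3 of the 9 called under both quantile normalization and the deposited values. The choice of the pairs may account for the calls, since 0 of the 9 were called with pairs set without the agent labels, and an effect of DHT stays open as untested.

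Of the probes higher at 12 h than at 6 h in controls, 1198 were called. Lower signal of the 12 h arrays is argued against as the whole cause by the DHT arrays, on which these probes were not chosen. There, 2 arrays of 12 h had a 75th percentile within the range at 6 h (2581 to 4103). Their lowest mean level was -3.29, above the highest at 6 h, -4.28. Both of them, DHT replicates 3 and 4, lay on slide 7. DHT arrays also pair in part with the controls on which the probes were chosen, so this is no independent check. A part may still come from lower signal, since the median change of all tested probes below -4 was 0.22 on these 2 arrays and 0.33 on all DHT arrays of 12 h, while over the 8 arrays of 12 h the level of the called probes and the log2 75th percentile had r = -0.58 (exact p = 0.132, two-sided), rho = -0.33 (exact p = 0.428) and r = -0.41 without the 2 arrays farthest from the median. Scaling to the 75th percentile stays open: 100% of these probes stayed above 0 under quantile normalization and under the deposited values, but these scalings move the median of all probes by at most 0.14, less than the smallest called rise of 0.38, so that this share decides nothing, and 638 probes were called higher under quantile normalization. The batch of slides and scan days cannot be told apart from time, since 0 slides hold arrays of both times, and time in culture stays open as untested.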

How the results depend on the processing

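The fits with inferred pairs or scan day as a block and all values for the time comparisons in the DHT arrays were chosen after the data were seen. No paired analysis was possible from the labels because they carry no replicate numbers that pair arrays, so pairs as a block rest on inferred partners. The cause of each change below was not tested, except that fits to 1 arm or without an array rest on fewer arrays. With pairs inferred from group-centred values as a block, limma called 1 probe for DHT at 6 h and 9 in the average. For controls at 9 against 6 h (176), slide as a fixed block gave 357, slide as a random block 328, only control arrays 2, and leaving out 1 array 31 to 252. For controls at 12 against 6 h (1372), normexp gave 870, quantile normalization 848, the deposited values 788, and leaving out 1 array 848 to 1473. For DHT arrays at 9 against 6 h (109), only probes well above background on all arrays gave 192, slide as a fixed block 20, only DHT arrays 6, and leaving out 1 array 14 to 229. For DHT arrays at 12 against 6 h (1478), leaving out 1 array gave 1110 to 1416. Of 502 values of named probes under alternatives, 464 kept their direction and side of the threshold, 38 no longer passed and 0 reversed. Most of the 502 belong to DHT comparisons, where no named probe passed, so that keeping the side means only that it was still not called. All 38 belong to the probes called for time. Among these, lost calls ranged from 0 of 15 settings for UF_Ppr_AF_107870 and 0 of 14 for UF_Ppr_AF_116905 to 8 of 15 for UF_Ppr_AF_117886 and 11 of 14 for UF_Ppr_AF_116751. Slide as a fixed block could not be fitted for 12 against 6 h, since no slide holds both times, and the alternatives for gene lists were not run, since the files do not pair probes with genes. Signal over background limits the dim probes, with 10015 of the 13714 tested well above background on all arrays.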
